A study of Homo sapiens with 16 samples.

How the data were processed

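Messenger RNA was measured in MDA-MB-231 and SUM159PT cells 48 h after transfection with Lipofectamine 2000 and an siRNA against YES1 or firefly luciferase, with medium added at 6 h and changed at 24 h, per the labels' protocols. There were 16 libraries, 4 for each of the 4 groups, which the design text calls technical replicates. Polyadenylated RNA was selected on poly-T beads and copied with random hexamers, per the labels' protocols, which do not settle whether the libraries kept the strand. Reads were aligned to hg38 with HISAT2 2.0.5 and counted per gene with featureCounts 1.5.0-p3, per the submitters' processing notes. The authors deposited these values as raw integer counts, with 1 table for each line. Columns of the SUM159PT table carry the prefix S149, which does not abbreviate SUM159PT and could stand for another breast cancer line, SUM149. The titles and cell line labels give SUM159PT, which is used here, and the identity of the line was not tested. The annotation release and the strand setting of the counting step are not given in the sources used here, so counts of overlapping or antisense genes and of near-identical gene copies are uncertain.

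All 58735 gene IDs of the tables were found in GENCODE 29 (Ensembl 94), which gave symbols, biotypes and GRCh38 coordinates. 26050 genes had 0 counts in every library. All 988 members of 31 gene lists were matched to gene IDs. Depth was 15680459 to 23451253 counts per library. Between libraries of a group the chi-squared per degree of freedom ran from 2.15 to 44.7, so no libraries were duplicates, and the common biological coefficient of variation was 0.0988 in MDA-MB-231 and 0.165 in SUM159PT.

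Tests, alternatives, gene lists and the rule for named genes were set before the data were examined. Each line was fitted on its own 8 libraries in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter and the quasi-likelihood F test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes come from that fit. The difference between lines was the interaction of line and siRNA over all 16 libraries. The shared response was the overlap of the calls in the 2 lines among genes tested in both, with one-sided Fisher's exact tests, and correlations across genes. Gene lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists. Members were counted as risen or fallen by their adjusted p over all genes, and again with the adjustment over the list alone. Percent of YES1 remaining is the ratio of mean CPM.

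Genes were named by a fixed rule: YES1, 11 key genes, the 5 rising and 5 falling coding genes with the largest log2 fold change per line among those at 5 CPM or more whose groups did not overlap, and up to 3 members of each called list. For the interaction and the overlap the 5 largest of each sign at 5 CPM or more in both lines were named, the overlap ranked by the smaller of the 2 log2 fold changes without YES1. Interaction values are also given for genes named in a line. Some genes that the rule names are not reported here. Which of the others the text discusses was decided after their values were seen.

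The scripts were tested on simulated data with 50 changed genes at each size. At 1.25, 1.5, 2 and 4-fold the fit recovered 28%, 70%, 90% and 96% in MDA-MB-231, 4%, 36%, 64% and 90% in SUM159PT, and 2%, 34%, 48% and 78% for the interaction. Of the unchanged genes 9, 8 and 7 were called. In these simulations changes of 2-fold and less were often missed in SUM159PT and in the interaction. Few genes were changed there, while 36.8% of genes in SUM159PT and 24.3% in the interaction were called in the data. An adjusted p is harder to pass when few genes change, so these shares do not measure what was missed in the data. A simulated 1.5-fold shift of 1 list was called in each comparison, with 0 other lists called. The genes were simulated as independent, so this does not measure false calls of lists whose genes vary together. In the data the estimated correlation was 0.401 for the FOXM1-linked list in MDA-MB-231.

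The alternatives were RLE scaling, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, replicate number as a block, leaving out each library, a joint fit of all 16 libraries and glmTreat at 1.5-fold. For lists they were an estimated correlation, the voom scale and fry, which tests a list against no change and so asks another question than camera, which compares a list with the other genes. After the data were seen, total counts as the scaling, scaling factors set within each line for the interaction, and fry, the filters and leaving out libraries for the interaction of lists were added. As a further check, each 7-base word in 3' UTRs of at least 50 bases was regressed on the log2 fold change of 11039 coding genes, and words within the first 5 in both lines were kept. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.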

Results

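The series measured messenger RNA in 2 human cell lines, MDA-MB-231 and SUM159PT, both established from triple-negative breast cancer, a form that lacks the estrogen and progesterone receptors and amplified HER2. Cells were collected 48 h after transfection with an siRNA against YES1 (siYES1) or a control siRNA against firefly luciferase (siNS). YES1 is a tyrosine kinase of the Src family, and the series' title ties it to centrosome homeostasis, chromosomal stability and response to therapy. Each line had 4 libraries per siRNA, 16 in all. The columns of the SUM159PT table carry a prefix that could stand for another line, so the name of this line rests on the titles and labels. The design text calls these technical replicates, so every p-value here measures only the spread between such samples. Counts over all genes summed to 15863961 to 21158617 per library in MDA-MB-231 and to 15680459 to 23451253 in SUM159PT. The first principal component separated siYES1 from siNS in both lines, with 67.8% of the variance in MDA-MB-231 and 53.1% in SUM159PT. On the second component of SUM159PT, which took 13.96%, siNS replicate 1 lay at 47.6 and the other 3 siNS libraries between -32.9 and -11.1.

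YES1 transcripts were lower in all 4 siYES1 libraries than in all 4 siNS libraries of each line. The YES1 gene (ENSG00000176105, protein-coding) lies on chromosome 18 at 721588 to 812546 on the minus strand of GRCh38. In MDA-MB-231 its level was 63.2 ± 6.16 CPM (counts scaled for library size; mean ± SD, n = 4) with siNS and 13.8 ± 0.82 with siYES1, so that 21.8% remained. The log2 fold change was -2.20 ± 0.09 (SE; edgeR adjusted p = 5.25e-11). In SUM159PT the level was 134 ± 23.8 CPM with siNS and 17.2 ± 1.80 with siYES1, so that 12.9% remained, with a log2 fold change of -2.96 ± 0.14 (edgeR adjusted p = 3.88e-08). The fall was deeper in SUM159PT by 0.66 log2 units in the test of the difference between lines (log2 difference -0.66, edgeR adjusted p = 0.00657).

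**Figure D1:**
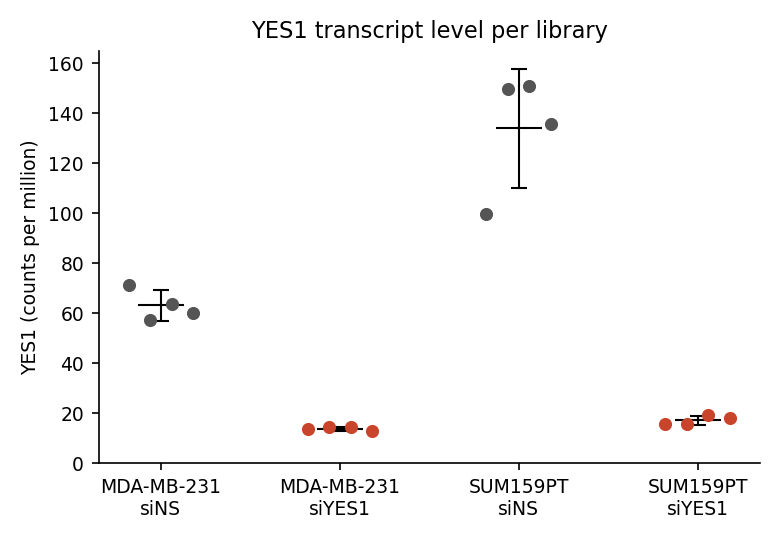
YES1 transcript level in CPM (vertical axis) in each of the 16 libraries (points) of the 4 groups (horizontal axis), with the mean and SD of each group of 4 as lines. The siYES1 libraries lie between 12.7 and 14.5 CPM in MDA-MB-231 and between 15.7 and 19.4 CPM in SUM159PT, below every siNS library of their line.

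The first comparison asked which transcripts changed with siYES1 in MDA-MB-231. Transcripts of cell division stood higher with siYES1 than with siNS. Among 62 tested FOXM1-linked G2/M genes, which cells use to enter and complete mitosis, 61 rose and 0 fell, with a median log2 fold change of 1.00 (62 rose when adjusted over the list alone). PLK1, a kinase of mitotic entry, rose by 1.60 ± 0.07 log2 units (SE), from 60.4 to 183 CPM. CKS1B, a subunit of cyclin-dependent kinases, rose by 1.76 ± 0.10, and cyclin B1 (CCNB1) rose by 1.12 ± 0.09. The kinases AURKA and AURKB rose by 0.89 and 1.08, and the transcription factor FOXM1 itself by 0.87. The camera adjusted p of this list was 6.62e-30, with an adjusted p of 0.126 with an estimated correlation.

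Genes of DNA replication and repair rose in the same cells. Of 56 E2F-regulated replication genes, 53 rose and 0 fell, with a median log2 fold change of 0.74. DTL, a receptor of the CRL4 ubiquitin ligase, rose by 1.66, and GINS1, a part of the replicative helicase, by 1.41. Among 42 genes of homologous recombination and the Fanconi pathway, 33 rose and 1 fell, with a median of 0.64. FANCD2 rose by 1.96 ± 0.10, EME1 by 1.54 and RAD54B by 1.40. Of 39 kinetochore and spindle checkpoint genes, 32 rose and 2 fell, with a median of 0.83, and SGO1, which protects sister chromatid cohesion, rose by 1.24. Among 53 genes of centriole duplication and the centrosome, 33 rose, 3 fell and 17 were not called, with a median of 0.36. CEP152, a scaffold of centriole duplication, rose by 1.08, CENPJ by 1.02 and PLK4, the kinase that starts it, by 0.99. Camera gave adjusted p = 1.86e-20 for the replication list, 4.5e-11 for repair, 3.63e-13 for the kinetochore and 8.59e-06 for the centrosome. Each of these 4 lists had an adjusted p of 0.126 with an estimated correlation. Adjusted over the list alone, the counts of the 4 lists were the same.

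Lists of ribosome genes were also called higher in MDA-MB-231, by smaller amounts. Of 61 cytosolic ribosomal protein genes, 26 rose and 0 fell, with a median of 0.19, among them RPS12 by 0.64 and RPL9 by 0.56. The camera adjusted p was 0.000165, with an adjusted p of 0.684 with an estimated correlation and 0.0769 by fry. Of 34 genes of ribosome biogenesis and MYC targets, 18 rose and 0 fell, with a median of 0.24, and DKC1, which modifies ribosomal RNA, rose by 1.20. Here the camera adjusted p was 0.000217, with an adjusted p of 0.126 with an estimated correlation. Ribosomal protein genes share reads with many pseudogene copies, so their single values are uncertain.

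Lists of hypoxia, junction, matrix and histone genes were called lower in MDA-MB-231. Of 35 hypoxia and glycolysis genes, 19 fell and 2 rose, with a median of -0.23. The carbonic anhydrase CA9 had a log2 fold change of -3.67 (3.26 to 0.25 CPM), the glycolytic aldolase ALDOC -1.63 and the angiogenic factor VEGFA -1.14. The camera adjusted p was 0.000682, with an adjusted p of 0.167 with an estimated correlation. Of 22 epithelial junction genes, 11 fell and 2 rose, with a median of -0.41. The protease inhibitor SPINT1 changed by -2.66 log2 units and plakoglobin (JUP) by -1.35. Camera gave this list an adjusted p of 0.00162, with an adjusted p of 0.23 with an estimated correlation. Of 26 mesenchymal genes, 11 fell and 3 rose (13 fell adjusted over the list alone), with a median of -0.25, among them the collagens COL1A1 and COL5A1 at -1.15 each and the matrix protein SPARC at -1.81. This call was near the threshold, with a camera adjusted p of 0.0468 and an adjusted p of 0.16 with an estimated correlation, and it ended without siNS replicate 3 (adjusted p = 0.059). Of 12 histone genes, 7 fell and 3 rose, with a median of -0.74, and HIST2H2BE changed by -2.04 and HIST1H2BD by -1.61. By camera the adjusted p was 0.0114, with an adjusted p of 0.126 with an estimated correlation. The libraries were made from polyadenylated RNA, and most histone transcripts of S phase carry no poly-A tail, so this list measures the tailed fraction.

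Of 7 tested genes of the Src family list in MDA-MB-231, which does not include YES1, 2 rose and 4 fell, and the list was not called (camera adjusted p = 0.394). Among them, FYN (ENSG00000010810, chromosome 6, 111660332 to 111873452, minus strand) had a log2 fold change of -1.04 ± 0.08 (edgeR adjusted p = 2.2e-08). SRC (ENSG00000197122, chromosome 20, 37344685 to 37406050, plus strand) had -0.66 ± 0.11 (edgeR adjusted p = 8.77e-05) and LYN -0.34 ± 0.08 (edgeR adjusted p = 0.00201). The Hippo pathway coactivator YAP1 rose by 0.65 ± 0.09. The cell cycle inhibitor CDKN1A rose by 0.26 ± 0.07 (edgeR adjusted p = 0.00817), a call that ended in a joint model of all 16 libraries (adjusted p = 0.106). The largest rises were sought among coding genes at a mean of 5 CPM or more whose groups did not overlap. They were in ID3, an inhibitor of basic helix-loop-helix factors (2.84, from 9.96 to 71.4 CPM), and the nuclear lamin LMNB1 (2.28). ATOH8 (2.27, from 3.01 CPM), PLSCR4 (2.23, from 2.97 CPM) and the G1 kinase CDK6 (2.10) followed. EDN2, which encodes endothelin 2, had a log2 fold change of -3.08 (41.5 to 4.89 CPM), SPINK4 -2.95 and CPT1C -2.92, and MPP4 and ABI3BP also fell. Across all genes, 7503 of 14319 tested genes (52.4%) changed, 3570 rising and 3933 falling, and 1462 of them by 2-fold or more (450 rising, 1012 falling). Over all tested genes, called or not, the siYES1 and siNS libraries did not overlap in 6745 (47.1%), against 2.86% by chance. The 3' UTRs of FYN, ABI3BP and COL5A1 hold a 7-base word that went with lower log2 fold changes in both lines. Those of CDK6, YAP1, PLK4, CDKN1A, ATOH8, CKS1B, DTL, SPINT1, DKC1 and HIST2H2BE hold a word that went with higher ones, and SRC and COL1A1 hold words of both kinds.

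The second comparison asked the same of SUM159PT. Mitotic genes rose here too. Of 62 FOXM1-linked G2/M genes, 53 rose and 0 fell (56 rose adjusted over the list alone), with a median log2 fold change of 0.79. PLK1 rose by 1.53 ± 0.14 (SE; 53.5 to 154 CPM), cyclin A2 (CCNA2) by 1.34 ± 0.10, CCNB1 by 1.18, AURKA by 1.06 and AURKB by 0.96. Camera gave an adjusted p of 1.25e-25, with an adjusted p of 0.256 with an estimated correlation. FOXM1 itself was not called (log2 fold change 0.29 ± 0.17, edgeR adjusted p = 0.204), but was called without siNS replicate 1 (adjusted p = 0.000915) and with no filter on low counts.

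Lists of centrosome, kinetochore and microtubule genes were called higher in SUM159PT, although most of their members were not called. Of 54 centriole and centrosome genes, 19 rose and 2 fell, with a median of 0.20, among them CENPJ by 0.99, CEP152 by 0.85 and HAUS6, a subunit of augmin, by 0.82, and PLK4 rose by 0.76. Over this list camera gave an adjusted p of 0.00296, with an adjusted p of 0.171 with an estimated correlation. Of 39 kinetochore genes, 14 rose and 1 fell, with a median of 0.25, and SGO1 rose by 1.13. For the list as a whole the camera adjusted p was 0.00296, with an adjusted p of 0.57 with an estimated correlation, and without siNS replicate 1 the counts were 21 and 1 with a median of 0.43. Of 33 tubulin and microtubule genes, 14 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 0.20. TUBA1C rose by 0.89 and NDEL1, a dynein regulator, by 0.80, and VASH2, which removes the terminal tyrosine of tubulin, changed by -1.51. Tested as a group, these genes had a camera adjusted p of 0.00661, with an adjusted p of 0.256 with an estimated correlation. With total counts as the scaling, 12 rose and 6 fell among centrosome genes (median 0.03) and 9 and 3 among kinetochore genes (0.07). Among the tubulin and microtubule genes 10 rose and 5 fell with that scaling (0.02). TUBA1C and TUBA1A are near-identical in sequence, so their values are uncertain.

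Replication genes were not called as a list in SUM159PT. Of 56 E2F-regulated genes 7 rose, 10 fell and 39 were not called, with a median of -0.29 (camera adjusted p = 0.586). The direction turned without siNS replicate 1, when 11 rose and 8 fell with a median of 0.15. Among 42 repair genes 9 rose and 2 fell, with a median of 0.03 (camera adjusted p = 0.178), against 18 and 3 and a median of 0.28 without that library. With total counts as the scaling the medians were -0.48 for replication, with 3 rising and 13 falling, and -0.14 for repair, with 3 and 3, so the direction of the repair list turned.

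Lists of lysosome and stress response genes were called higher in SUM159PT. Of 36 lysosome and autophagy genes, 20 rose and 3 fell (23 and 3 adjusted over the list alone), with a median of 0.32. The lysosomal membrane protein LAMP1 rose by 1.46 ± 0.10 and the autophagy receptor SQSTM1 by 1.08 ± 0.13. By camera the adjusted p was 2.13e-05, with an adjusted p of 0.358 with an estimated correlation. Of 33 ATF4 target genes, 21 rose and 3 fell (22 and 3 adjusted over the list alone), with a median of 0.42, among them TRIB3 by 1.15 and the cystine transporter SLC7A11 by 1.07. Over this list camera gave an adjusted p of 4.73e-05, with an adjusted p of 0.276 with an estimated correlation. Of 24 unfolded protein response genes, 10 rose and 0 fell, with a median of 0.19, and the stress sensor ERN1 rose by 1.13 and HERPUD1 by 0.88. For the list as a whole the camera adjusted p was 0.0136, with an adjusted p of 0.574 with an estimated correlation. That call ended with total counts as the scaling (0.129), when 4 rose and 7 fell with a median of 0.02, and fry, which tests a list against no change, gave 0.0538. With the same scaling 13 lysosome genes rose and 6 fell (median 0.15), and 12 ATF4 targets rose and 4 fell (0.25).

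Lists of ribosomal, sterol, apoptosis and hypoxia genes were called higher as well. Of 61 ribosomal protein genes, 32 rose and 0 fell (38 adjusted over the list alone), with a median of 0.23, among them RPL10 by 0.43 and RPS6 by 0.41. Tested as a group, these genes had a camera adjusted p of 9.42e-09, with an adjusted p of 0.57 with an estimated correlation, and with total counts as the scaling 10 rose and 1 fell with a median of 0.06. Of 25 cholesterol synthesis genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.39. The sterol carrier STARD4 rose by 1.23, and the sterol reductase TM7SF2 changed by -1.97. By camera the adjusted p was 0.00296, with an adjusted p of 0.57 with an estimated correlation and 0.0739 by fry. Of 24 apoptosis regulators, 11 rose and 2 fell, with a median of 0.32, and the risers held HRK, which promotes cell death (1.23), and BCL2 (1.06) and CFLAR (0.73), which oppose it. Over this list camera gave an adjusted p of 0.00799, with an adjusted p of 0.276 with an estimated correlation. Of 35 hypoxia and glycolysis genes, 14 rose and 6 fell (15 and 6 adjusted over the list alone), with a median of 0.26. Adrenomedullin (ADM) rose by 1.05, but ANGPTL4 and the oxygen sensor EGLN3, both known hypoxia targets, changed by -1.79 and -1.51. For the list as a whole the camera adjusted p was 0.0298, with an adjusted p of 0.57 with an estimated correlation. This call ended with total counts as the scaling (0.0758, when 7 rose and 8 fell with a median of 0.10) and without siNS replicate 1 (0.0606, median 0.16), and fry gave 0.0866. Scaled by total counts, 4 cholesterol genes rose and 1 fell (median 0.23) and 8 apoptosis regulators rose and 3 fell (0.15), and without siNS replicate 1 the cholesterol median was 0.25.

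Lists of epithelial, interferon, mitochondrial and fibroblast genes were called lower in SUM159PT. Of 16 epithelial junction genes, 8 fell and 1 rose, with a median of -0.91, and JUP changed by -2.38 ± 0.11 (154 to 29.7 CPM) and SPINT1 by -1.66. Tested as a group, these genes had a camera adjusted p of 0.00914, with an adjusted p of 0.256 with an estimated correlation. Of 37 type I interferon response genes, 13 fell and 2 rose, with a median of -0.32, among them IFI44L at -1.93 and MX2, an antiviral GTPase, at -1.77. By camera the adjusted p was 0.01, with an adjusted p of 0.276 with an estimated correlation. Of 13 transcripts of the mitochondrial genome, 6 fell and 0 rose (7 fell adjusted over the list alone), with a median of -0.27, and MT-CYB changed by -0.60 and MT-ND2 by -0.42. Over this list camera gave an adjusted p of 0.00647, with an adjusted p of 0.57 with an estimated correlation. Of 5 tested fibroblast markers, 3 fell and 0 rose (4 fell and 1 rose adjusted over the list alone), with a median of -1.39. These were the growth factor receptors PDGFRA (-1.70) and PDGFRB (-1.51) and the collagen COL1A1 (-1.39, from 1625 to 619 CPM). For the list as a whole the camera adjusted p was 0.00691, with an adjusted p of 0.276 with an estimated correlation. Scaled by total counts, 16 interferon genes fell and 1 rose (median -0.50), and 11 mitochondrial transcripts fell and 0 rose (-0.45).

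The largest rises among coding genes of SUM159PT at a mean of 5 CPM or more, chosen in the same way, were in unrelated families. The transcription factor KLF2 rose by 3.05 ± 0.27 (2.78 to 23.3 CPM), the acyltransferase GPAT3 by 2.11 ± 0.13, the pregnancy glycoprotein gene PSG4 by 1.86, CLDN12 by 1.76 and the repressor E2F7 by 1.73. PSG4 belongs to a family of close copies, so its value is uncertain. The stathmin STMN4 had a log2 fold change of -5.92 ± 0.26 (37.7 to 0.62 CPM), the myosin-binding protein MYBPC1 -4.88 and the scavenger receptor SCARA5 -4.81, followed by LMTK3 (-4.33) and C5AR2 (-3.94). CDKN1A rose by 1.04 ± 0.11 (edgeR adjusted p = 1.05e-05) and YAP1 by 0.55 ± 0.07. LYN changed by -0.34 ± 0.09 (edgeR adjusted p = 0.01). SRC was not called (-0.03 ± 0.09, edgeR adjusted p = 0.843), and FYN passed narrowly (-0.20 ± 0.08, edgeR adjusted p = 0.0483), a call lost in 11 of its 16 alternatives (adjusted p 0.0596 to 0.212), 7 of which each left out 1 library. Across all genes, 5321 of 14469 tested genes (36.8%) changed, 2566 rising and 2755 falling, and 1337 of them by 2-fold or more (215 rising, 1122 falling). Risers made up 48.2% of the calls, but 25.0% with total counts as the scaling, which moved the median log2 fold change of all genes by -0.17. The 3' UTRs of IFI44L and FYN hold a word that went with lower log2 fold changes in both lines. Those of GPAT3, CLDN12, E2F7, HAUS6, CCNA2, ERN1, SLC7A11, EGLN3, ADM, RPL10, LAMP1 and PDGFRB hold a word that went with higher ones. EGLN3 and PDGFRB nevertheless fell, and HERPUD1 and CFLAR hold both kinds. Such words are common among the other searched genes, as given above.

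**Figure D2:**
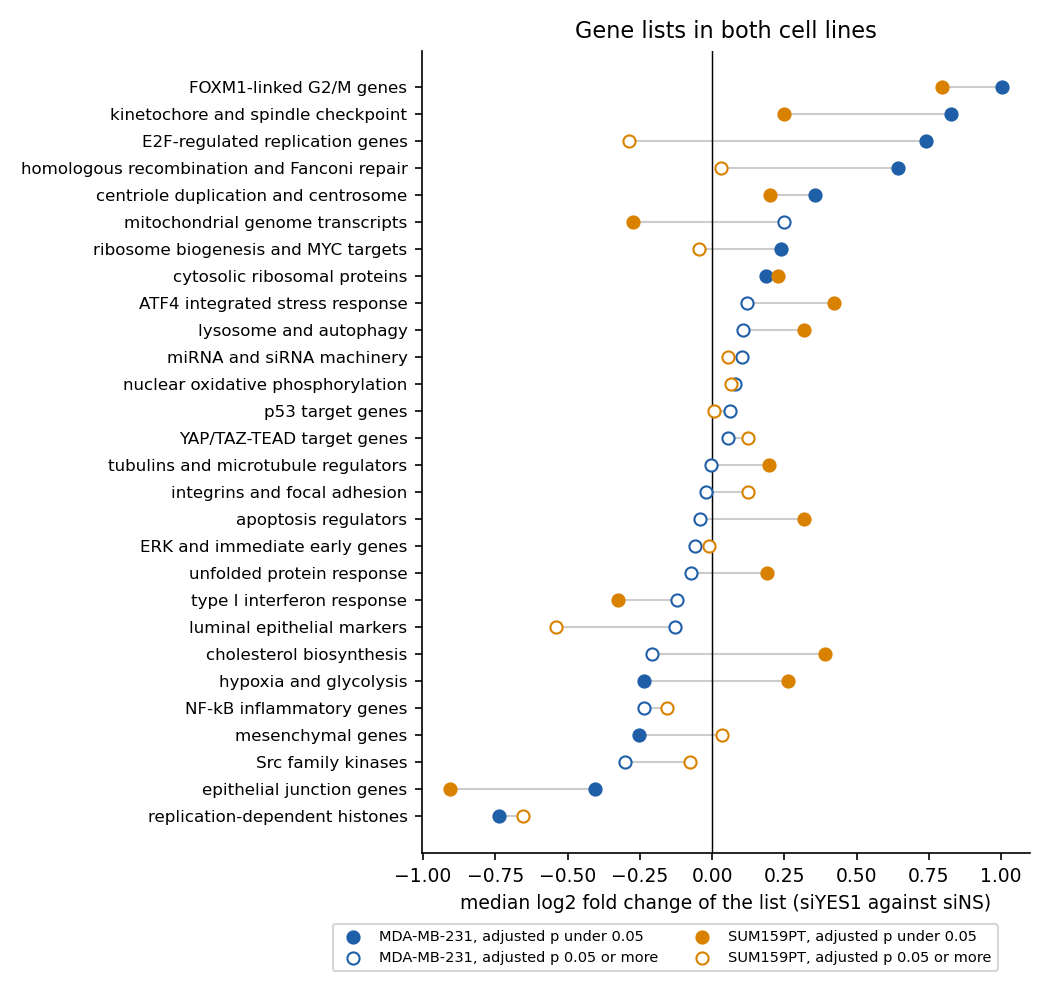
Median log2 fold change of siYES1 against siNS (horizontal axis) for the 28 gene lists tested in both lines (vertical axis), with MDA-MB-231 in blue and SUM159PT in orange. Filled points had a camera adjusted p under 0.05; the FOXM1-linked list lies at 1.00 and 0.79, and the E2F-regulated list at 0.74 and -0.29.

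The third comparison asked where the response to siYES1 differed between the lines, by the interaction of line and siRNA over all 16 libraries. Replication genes differed most in number of members: 33 of 56 E2F-regulated genes responded lower in SUM159PT than in MDA-MB-231 and 0 higher (45 lower adjusted over the list alone), with a median difference of -0.86 log2 units. UHRF1, which keeps DNA methylation through replication, differed by -1.60 and was not called in SUM159PT (-0.40, edgeR adjusted p = 0.33), and DTL, which rose in both lines, differed by -0.68. Tested as a group, these genes had a camera adjusted p of 5.48e-14, with an adjusted p of 0.367 with an estimated correlation, and without SUM159PT siNS replicate 1 the median was -0.62 with 33 members lower. Among 42 repair genes 11 responded lower and 0 higher (12 lower adjusted over the list alone), with a median of -0.41, and FANCD2 differed by -1.10. Here the camera adjusted p was 1.87e-05, with an adjusted p of 0.495 with an estimated correlation, and with total counts as the scaling 23 were lower (median -0.63). The FOXM1-linked list was not called, with 7 members lower and 2 higher and a median of -0.07 (camera adjusted p = 0.105). Its counts were 18 lower and 1 higher with total counts as the scaling (median -0.29), and 10 lower and 1 higher with scaling factors set within each line (-0.17).

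Lists of hypoxia, lysosome and secretory stress genes were called as responding higher in SUM159PT than in MDA-MB-231. Among 35 hypoxia and glycolysis genes 23 responded higher and 1 lower (26 and 1 adjusted over the list alone), with a median of 0.57, among them ADM by 1.42 and VEGFA by 1.30. CA9, which fell in both lines but less in SUM159PT, differed by 2.91. By camera the adjusted p was 1.29e-07, with an adjusted p of 0.319 with an estimated correlation. Among 36 lysosome and autophagy genes 18 responded higher and 0 lower (19 adjusted over the list alone), with a median of 0.38, led by WIPI1, an autophagosome protein, at 2.63. Among 24 unfolded protein response genes 14 responded higher and 0 lower (16 adjusted over the list alone), with a median of 0.36, among them HERPUD1 by 0.89. Both lists had a camera adjusted p of 1.87e-05, with an adjusted p of 0.367 with an estimated correlation. Among 33 ATF4 target genes 13 responded higher and 3 lower (16 and 4 adjusted over the list alone), with a median of 0.33, and TRIB3 differed by 2.01. Over this list camera gave an adjusted p of 0.0122, with an adjusted p of 0.367 with an estimated correlation. Among 25 cholesterol genes 11 responded higher and 0 lower (13 adjusted over the list alone), with a median of 0.51, and STARD4 differed by 1.19. For the list as a whole the camera adjusted p was 0.00107, with an adjusted p of 0.504 with an estimated correlation. With total counts as the scaling these calls stayed, with fewer members: 14 higher and 2 lower for hypoxia (median 0.36), 9 and 2 for lysosome (0.16), 8 and 1 for the unfolded protein response (0.15), 9 and 4 for ATF4 (0.12) and 7 and 0 for cholesterol (0.30). Without SUM159PT siNS replicate 1 the medians were 0.25 for lysosome, 0.20 for ATF4 and 0.24 for cholesterol.

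The list of tubulins and microtubule regulators was the only one whose difference between lines passed with an estimated correlation. Among 33 members 14 responded higher in SUM159PT and 0 lower (15 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 9.92e-05, and adjusted p = 0.0499 with an estimated correlation). Of the members of this list 8 were higher and 2 lower with total counts as the scaling (median 0.09). TUBA1A differed by 2.61, since it changed by -2.85 in MDA-MB-231 and was not called in SUM159PT (-0.34, edgeR adjusted p = 0.0539, under 0.05 in 9 of its 16 alternatives). Among 39 kinetochore genes 7 responded lower and 1 higher, with a median of -0.29 (camera adjusted p = 0.000498, adjusted p = 0.504 with an estimated correlation, 0.0805 by fry). Among 13 mitochondrial transcripts 3 responded lower and 0 higher (6 lower adjusted over the list alone), with a median of -0.42, and MT-CYB differed by -0.72 (camera adjusted p = 0.00601, adjusted p = 0.575 with an estimated correlation, 0.117 by fry). Among 32 mesenchymal genes 13 responded higher and 3 lower, with a median of 0.33, and SPARC differed by 1.72 (camera adjusted p = 0.0219, adjusted p = 0.504 with an estimated correlation). That call ended without SUM159PT siNS replicate 1 (0.0586). Among 34 ribosome biogenesis genes 7 responded lower and 2 higher (8 and 2 adjusted over the list alone), with a median of -0.19, and DKC1 differed by -0.56 (camera adjusted p = 0.0219, adjusted p = 0.596 with an estimated correlation). By fry the adjusted p was 0.295, and the call ended without MDA-MB-231 siNS replicate 3 (0.0503) or SUM159PT siNS replicate 1 (0.0645). Among 26 apoptosis regulators 9 responded higher and 1 lower, with a median of 0.25, and CFLAR differed by 0.73 (camera adjusted p = 0.0445, adjusted p = 0.367 with an estimated correlation). This last call ended in 8 further alternatives, 4 of which each left out 1 library (MDA-MB-231 siNS replicate 3, 0.0599; SUM159PT siNS replicate 1, 0.0625, siNS replicate 4, 0.0514, and siYES1 replicate 1, 0.0621). With total counts as the scaling the medians were -0.51 for the kinetochore (17 lower, 1 higher), -0.65 for mitochondrial transcripts (9 and 0), 0.12 for mesenchymal genes (9 higher, 5 lower), -0.41 for ribosome biogenesis (13 lower, 1 higher) and 0.03 for apoptosis regulators (5 higher, 4 lower). Scaling factors set within each line gave -0.29 for ribosome biogenesis and 0.15 for apoptosis regulators, and leaving out SUM159PT siNS replicate 1 gave -0.12 and 0.16.

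Several genes went opposite ways in the lines. The matrix protein gene ABI3BP changed by -3.00 in MDA-MB-231 and rose by 0.63 in SUM159PT (difference 3.73 ± 0.23 SE). WIPI1 changed by -1.65 and rose by 0.89. The lincRNA AC091182.2 changed by -1.50 and rose by 1.04. PLEKHA6 rose by 0.45 in MDA-MB-231 and changed by -2.93 in SUM159PT (difference -3.28), and NFE2L3 rose by 1.60 and changed by -0.88. LMTK3 fell in both lines, but further in SUM159PT (difference -3.33). ID3 rose only in MDA-MB-231 (difference -2.81) and GGT5 fell only in SUM159PT (difference -2.65). SRC differed by 0.73 (edgeR adjusted p = 0.00115), FYN by 0.93 (2.36e-06) and CDKN1A by 0.88 (5.22e-05), and FOXM1 did not pass (-0.48, adjusted p = 0.0723). In all, 3953 of 16299 tested genes differed, 2511 (63.5%) responding higher and 1442 lower in SUM159PT. That share was 33.0% with total counts as the scaling and 49.0% with scaling factors set within each line, which moved the median of all genes by -0.22 and -0.10. The 3' UTR of WIPI1 holds a word that went with lower log2 fold changes in both lines. Those of UHRF1, PLEKHA6 and NFE2L3 hold a word that went with higher ones. In MDA-MB-231 these genes changed in the direction of their word. In SUM159PT WIPI1 rose and PLEKHA6 and NFE2L3 fell, against that direction. ABI3BP, which holds a word that went with lower values, also rose there.

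The fourth comparison asked how far the lines shared a response. Of 12689 genes tested in both, 3062 were called in both, 2599 of them (84.9%) in the same direction and 463 in opposite directions. Genes that rose in both numbered 1205, against 659 expected of independent lists, and genes that fell in both 1394, against 627 (one-sided Fisher's exact test, p = 6.29e-155 and 2.29e-309, with genes taken as independent). At 2-fold or more in both lines there were 344. Across genes the log2 fold changes had Pearson r = 0.459 and Spearman rho = 0.407, and r = 0.686 among genes called in both. Genes are not independent replicates, and no p is given. With no filter on low counts Pearson r was 0.154. Each line has its own control libraries, and the labels name the same siRNA targets for both lines.

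Genes called in both lines at 5 CPM or more were ranked by the smaller of their 2 log2 fold changes, with YES1 set aside. By that rank the largest shared rises were in PLSCR4 (2.23 in MDA-MB-231 and 1.58 in SUM159PT), GPAT3 (1.69 and 2.11), CLDN12 (1.60 and 1.76), TTPAL (1.58 and 1.73), a paralogue of the alpha-tocopherol transfer protein, and HINT3 (1.56 and 1.59). By the same rank the largest shared falls were in GNPTAB, an enzyme of the mannose 6-phosphate tag of lysosomal proteins (-2.34 and -1.90), SYT12 (-2.05 and -3.09), the water channel AQP3 (-1.96 and -3.78), REEP6 (-1.78 and -1.74) and TM7SF2 (-1.78 and -1.97). Of these, the 3' UTRs of GPAT3, CLDN12 and TTPAL hold a word that went with higher log2 fold changes in both lines, and those of HINT3 and GNPTAB hold words of both kinds.

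**Figure D3:**
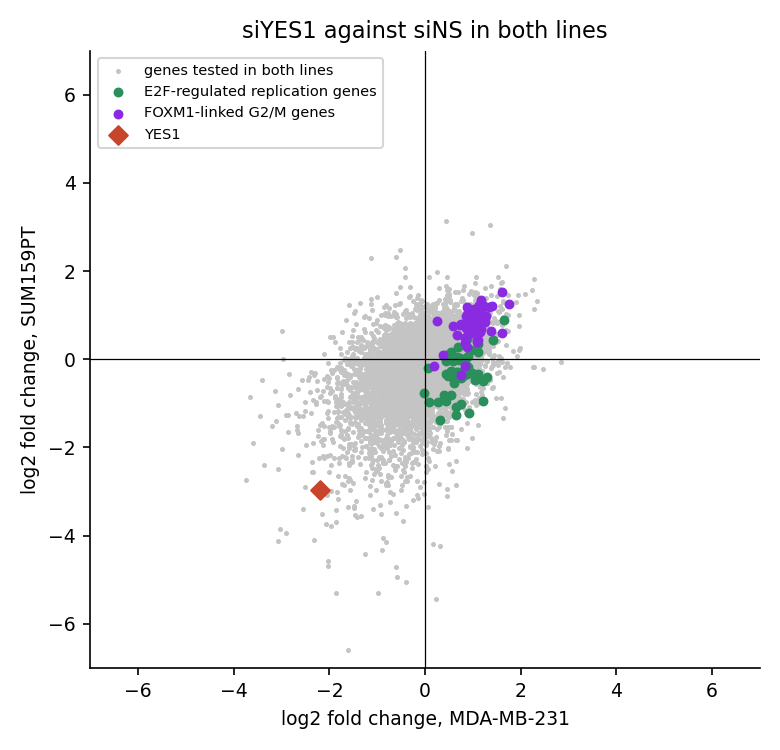
Log2 fold change of siYES1 against siNS in MDA-MB-231 (horizontal axis) and SUM159PT (vertical axis) for the 12689 genes tested in both lines (grey points). FOXM1-linked G2/M genes (purple) have medians of 1.00 and 0.79, E2F-regulated replication genes (green) 0.74 and -0.29, and YES1 (red) lies at -2.20 and -2.96.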

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

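The search for outlying libraries and for differences between lines was set before the data were examined, and the tests on words in 3' UTRs, on the E2F-regulated list and on the FOXM1-linked list were chosen only after the result was seen. Dixon's test compared each value with the other 3 of its group and picked 11 of 308 groups of 4, where chance alone picks about 1 in 20. SUM159PT siNS replicate 1 gave 6 of the 11: CEP152 at 9.22 CPM (others 14.2 to 14.7) and NDEL1 at 19.9 (33.0 to 35.5) lay low, and SGO2 at 35.6 (22.4 to 24.5), NUF2 at 26.3 (15.5 to 17.2), ANGPTL4 at 110 (52.5 to 59.4) and TUBA1A at 173 (111 to 119) lay high. Mitochondrial transcripts took 1.79% of counts in MDA-MB-231 siYES1 replicate 4 (others 1.45% to 1.496%) and 2.14% in SUM159PT siNS replicate 2 (2.46% to 2.50%). In SUM159PT siYES1, replicate 4 held 23.45 M counts (M for 10 to the power 6; others 19.69 to 20.01) and MT-ND2 at 612 CPM (539 to 549), and replicate 3 held HERPUD1 at 256 CPM (287 to 292).

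The test of the interaction picked 3953 genes, 63 of the named genes and 13 lists as different between lines. Scaling factors set within each line moved the median difference of all genes by -0.10, and total counts as the scaling by -0.22. The size of the small differences below therefore depends on the scaling. Named genes that responded higher in SUM159PT by at least 1 log2 unit were ABI3BP 3.73, CA9 2.91, AC091182.2 2.64, WIPI1 2.63, TUBA1A 2.61, PSG4 2.37, EDN2 2.15, HIST2H2BE 2.06, TRIB3 2.01, KLF2 1.78, CPT1C 1.76, SPARC 1.72, ALDOC 1.62, ADM 1.42, VEGFA 1.30, STARD4 1.19 and SPINT1 1.11. Smaller differences of that sign were FYN 0.93, HERPUD1 0.89, CDS1 0.89, NDEL1 0.89, CDKN1A 0.88, SQSTM1 0.82, E2F7 0.78, ERN1 0.77, SRC 0.73, CFLAR 0.73, TUBA1C 0.72, SYVN1 0.71, SLC7A11 0.65, GNPTAB 0.54, LAMP1 0.53, GPAT3 0.52, RPS6 0.49, LAMP2 0.45 and COL5A1 0.36. Genes that responded lower were LMTK3 -3.33, PLEKHA6 -3.28, ID3 -2.81, GGT5 -2.65, C5AR2 -2.41, NFE2L3 -2.38, ATOH8 -2.36, HERC5 -2.29, IFI44L -2.02, AQP3 -1.72, UHRF1 -1.60, ELF3 -1.38, FANCD2 -1.10 and LMNB1 -1.03, and by less than 1 unit SYT12 -0.94, JUP -0.93, HMMR -0.92, ANGPTL4 -0.87, HAUS8 -0.82, MT-CYB -0.72, MT-ND2 -0.71, DTL -0.68, YES1 -0.66, DKC1 -0.56, CDK6 -0.53, CKS1B -0.41 and CAD -0.39. Lists higher in SUM159PT had median differences of 0.57 (hypoxia and glycolysis), 0.51 (cholesterol biosynthesis), 0.38 (lysosome and autophagy) and 0.36 (unfolded protein response). Below these came 0.33 (ATF4 targets), 0.33 (mesenchymal genes), 0.31 (tubulins and microtubule regulators) and 0.25 (apoptosis regulators). Lists lower in SUM159PT had -0.86 (E2F-regulated replication), -0.42 (mitochondrial transcripts), -0.41 (repair), -0.29 (kinetochore) and -0.19 (ribosome biogenesis).

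The rise of the FOXM1-linked list could reflect base composition, pairing of an siRNA seed with 3' UTRs, or scaling. After GC content and exon length were taken out, the median was 1.03 (bootstrap SE 0.028) in MDA-MB-231 and 0.92 (0.056) in SUM159PT. Over the 46 members without any of the listed words it was 0.97 and 0.81, and with total counts as the scaling 0.96 and 0.62. Each value stayed above 0.3 by more than 2 SE, the bound written before it was measured. Base composition, the listed words in the members' own 3' UTRs and the choice of scaling thus do not account for most of the rise. The SE resamples list members as independent, so it does not measure the spread between libraries. Other seeds, effects that run through other genes paired by an siRNA, and a change in total RNA per cell were not tested. A change in the share of cells in G2 and mitosis remains open, since no cell cycle profile was analysed here.

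The weaker response of E2F-regulated genes in SUM159PT could come from SUM159PT siNS replicate 1 or from base composition. Without that library the median difference went from -0.86 to -0.62 (SE 0.088), with 33 members lower, as many as with it, and after GC content and exon length were taken out it was -0.73 (SE 0.067). Both stayed below -0.3 by more than 2 SE. These SEs resample the list members as independent, so they do not measure the spread between libraries. The members had an estimated correlation of 0.546 in the interaction. Of 100 drawn pairs of splits of the libraries, 3 gave this list a median as large. Such pairs mix the siRNAs within each line, so they do not test for an equal response in the 2 lines.

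The response shared by the lines could come from GC content and length bias or from the siRNAs themselves, each of which pairs by its seed with other mRNAs. The correlation across genes was 0.459 before and 0.443 after GC content and length were taken out. It was 0.478 over genes with a searched 3' UTR against 0.46 over the 6573 without any listed word. Neither GC content and length nor the listed words in a gene's own 3' UTR thus account for most of it. Other seeds, and effects that run through other genes paired by an siRNA, were not tested. The siRNAs themselves are therefore not excluded as a source of the shared response. As a test of the genes that fell in both lines, words were ranked over all 11039 coding genes with a searched 3' UTR. A word present in YES1 mRNA ranked 1 in both lines among words tied to falling values. Of the 15286 words tested, 3878 occur in YES1 mRNA, so such a rank alone is weak evidence. The t of that word (-8.64 and -6.75) was smaller in size than that of the strongest rising word (11.7 and 8.71), and the test cannot tell. The strongest falling word (AGCAGTT) and the strongest rising word (AGCCTTA) were compared by number of sites in the 2 lines. In 4 of 4 comparisons the mean residual was larger with 2 or more sites than with 1, as seed pairing of the siRNAs would give. For AGCAGTT these differences were within their standard errors. TGCTAAT, not among these comparisons, went from -0.09 to -0.15 in MDA-MB-231 and from -0.08 to -0.06 in SUM159PT.

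The libraries of each line were also divided in every other way into 4 and 4, to ask whether chance could give counts as large. In MDA-MB-231 only 1 of 35 splits, the real one, gave 7503 genes or 1462 at 2-fold (highest other 0 for both), and in SUM159PT 1 of 35 gave 5321 and 1337 (highest other 0) so that by this test chance can be excluded for both lines at 1 in 35 and no lower. Every other split mixes siYES1 and siNS libraries within a group, which raises the spread, so the 0 of the other splits is no measure of false calls. None of this reaches beyond the libraries, which are technical replicates. For lists called, 5 of 35 splits reached the 11 of MDA-MB-231 (highest other 12). In SUM159PT 3 of 35 reached the 15 (highest other 16). Splits with unequal mixes of siYES1 and siNS libraries keep part of the siRNA effect. Outside the real split the FOXM1-linked median reached 0.541 in size in MDA-MB-231 and 0.51 in SUM159PT. Lists called in such splits may reflect the siRNA, so the test cannot decide whether chance gave the number of lists. Over 100 drawn pairs of splits of 2450, 1 reached the 2599 genes called the same way in both lines (highest other 0). Since every other split of a line called 0 genes, this result was fixed by the counts within the lines and adds nothing to them. For the 3953 genes of the interaction 1 reached the count (highest other 1865). These pairs mix the siRNAs within each line, so they test for any siRNA effect and not for an equal effect in both lines. They cannot exclude chance for a difference between lines. The correlation of 0.4586 was reached by 2 of 100 (highest other 0.4587). Pairs of splits that keep part of the siRNA effect can give a similar correlation, which does not depend on the size of the effect. The pair at 0.4587 may therefore be no measure of chance, and the test cannot decide for the correlation. The 13 interaction lists were reached by 9 of 100 (highest other 16). Pairs of splits that keep part of the siRNA effect may call lists too, so the test cannot decide for their number. The same limits hold for this number and for the medians of single lists that follow. Of the same 100, a median as large was seen in 34 for the kinetochore list, 25 for ribosome biogenesis and 12 for repair, for which chance cannot be excluded, 4 for ATF4 targets, 3 each for the E2F-regulated, mesenchymal and mitochondrial lists, 2 for apoptosis regulators, and 1, the real one, for hypoxia, lysosome, unfolded protein response, tubulins and cholesterol. Within a line it was seen in 5 of 35 splits for the SUM159PT kinetochore list (largest other 0.419), 3 for SUM159PT mitochondrial transcripts, 3 for MDA-MB-231 ribosomal proteins and 2 for SUM159PT cholesterol genes, so chance cannot be excluded for these lists.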

How the results depend on the processing

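The alternatives added after the data were seen (total counts as the scaling, scaling factors within each line, and further list tests of the interaction) were chosen only after the result was seen. Of 12 main results, 8 had the same outcome in every alternative, and no call of a main result, list or named gene turned direction. The correlation between lines fell to 0.154 with no filter, and the cause was not tested; leaving out 1 library it ran from 0.4262 (SUM159PT siNS replicate 2) to 0.4957 (SUM159PT siNS replicate 1). With an estimated correlation 0 lists were called in MDA-MB-231, 0 in SUM159PT and 1 in the interaction, and fry called 20 in MDA-MB-231. The cause was not tested. Leaving out each library gave 6725 to 7753 genes in MDA-MB-231, 4323 to 6237 in SUM159PT, 3349 to 4495 in the interaction and 2201 to 3094 shared, YES1 log2 fold changes of -2.25 to -2.13 and -3.08 to -2.90, and 10 to 12, 15 to 18 and 10 to 14 lists. The joint fit called 5898 and 6625 genes, and glmTreat 1770 and 1137. With replicate number as a block, 7109, 4961 and 3545 genes were called and 2404 shared, with r = 0.4606 and 10, 15 and 13 lists; the MDA-MB-231 mesenchymal list had an adjusted p of 0.0536. The numbers were not seen to pair samples: same-numbered libraries had deviations correlated at 0.0328, -0.123, -0.0507 and -0.0961 in MDA-MB-231 and -0.068, 0.0877, -0.038 and 0.00133 in SUM159PT, and best with their own number only for 1 number in each line. Of 153 named gene results, 144 kept their call in every alternative; those that did not were FYN, FOXM1, RPL26, CDKN1A, ELF3, HERC5, SYVN1, ASNS and TUBA1A.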

Other observations

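The word regression in the last paragraphs was planned before any word was seen, and the rule for which words to list was chosen only after the result was seen. Several pathways tied to Src kinases and growth control were not called in either line. Of 29 YAP/TAZ-TEAD target genes, 11 rose and 5 fell in each line, with medians of 0.05 in MDA-MB-231 and 0.12 in SUM159PT (camera adjusted p = 0.176 and 0.101). ERK and immediate early genes had 8 rising and 9 falling of 28 in MDA-MB-231 and 8 and 8 in SUM159PT (0.816 and 0.899). Integrin and focal adhesion genes had medians of -0.02 in MDA-MB-231, where the mean was 0.06, and 0.13 in SUM159PT (0.541 and 0.0759). The 7 tested Src family genes, YES1 not among them, had medians of -0.30 and -0.08 (0.394 and 0.758). Targets of p53 had medians of 0.06 and 0.01 with a mean of -0.06 in SUM159PT (0.541 and 0.661), although CDKN1A, a member, rose in both lines. NF-kB genes had medians of -0.23 and -0.15 (0.084 and 0.595), and the median difference between lines was 0.53 (0.189). With total counts as the scaling the SUM159PT medians turned to -0.05 for YAP/TAZ-TEAD targets, -0.04 for integrins and -0.16 for p53 targets, and those of ERK genes, the Src family and NF-kB genes were -0.17, -0.25 and -0.32. Without SUM159PT siNS replicate 1 they were 0.08 for YAP/TAZ-TEAD targets, 0.07 for integrins, -0.05 for ERK genes and -0.16 for the Src family.

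Further lists were not called in 1 line or in both. Nuclear oxidative phosphorylation genes had medians of 0.08 and 0.07 (camera adjusted p = 0.248 and 0.101), and with total counts as the scaling the SUM159PT median was -0.11. Genes of the miRNA and siRNA machinery, through which an siRNA acts, had medians of 0.10 and 0.05 (0.257 and 0.899), with a mean of -0.06 in SUM159PT, where total counts as the scaling gave a median of -0.12. In MDA-MB-231 cholesterol genes (-0.21, 0.512), the unfolded protein response (-0.07, 0.257), ATF4 targets (0.12, 0.217), lysosome genes (0.11, 0.355), tubulins (-0.003, 0.863), interferon genes (-0.12, 0.555), mitochondrial transcripts (0.25, 0.217) and apoptosis regulators (-0.04, with a mean of 0.005; 0.919) were not called. In SUM159PT mesenchymal genes (0.03, with a mean of -0.08; 0.899; -0.13 with total counts as the scaling), ribosome biogenesis (-0.04, with the test up; 0.661; -0.225 with total counts as the scaling) and histones (-0.66, 0.28) were not called. Without SUM159PT siNS replicate 1 the medians of mesenchymal genes (-0.03) and ribosome biogenesis (0.07, with 13 rising and 2 falling against 6 and 2) turned direction, and that of histones was -0.39. Luminal markers had medians of -0.13 and -0.54 (0.355 and 0.0619), and 5 tested endothelial markers in SUM159PT had -2.57, with 3 falling and 0 rising (0.055). Haematopoietic markers had under 5 tested members in each line and 5 in the interaction (0.442). Of the interaction lists, centrosome (0.442), p53 (0.851), YAP/TAZ-TEAD (0.568), ERK (0.945), integrins (0.0922), epithelial junctions (0.492), interferon (0.0922), oxidative phosphorylation (0.54), ribosomal proteins (0.332), miRNA machinery (0.476), Src family (0.476), histones (0.54), luminal (0.248), endothelial (0.105) and fibroblast markers (0.978) were not called.

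A hypothesis is that part of the shared response comes from seed pairing of the siRNAs. Of 11466 coding genes tested in both lines, 11039 (96.3%) had a 3' UTR of at least 50 bases, and 15286 words of 7 bases were tested, 3878 of them present in YES1 mRNA. Word t values correlated at 0.517 between lines. The strongest falling word was AGCAGTT (t = -8.64 and -6.75, 1598 genes), followed by TGCTAAT (-6.71 and -4.87, 1240 genes). Both occur in YES1 mRNA: AGCAGTT at chromosome 18, 756672 to 756678 (coding) and 722054 to 722060 (3' UTR), and TGCTAAT at 736896 to 736902 (coding), all on the minus strand of GRCh38. The siRNA sequences are not given in the labels, so whether either word is the site of the siRNA used cannot be read from the data.

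The words tied to rising values were stronger. AGCCTTA had t = 11.7 and 8.71 (1096 genes) and AAGCCTT 9.48 and 7.55, followed by TAGCCTT and AGCCTTT. A seed in the control siRNA would lower such genes in siNS cells, so that they would appear higher with siYES1. The words were picked on these same log2 fold changes, so their presence in genes that rose or fell is no further evidence. The mean residual for AGCCTTA went from 0.17 with 1 site to 0.26 with 2 or more in MDA-MB-231 and from 0.13 to 0.30 in SUM159PT. AGCCTTA and AAGCCTT also occur in YES1 mRNA, so presence there does not by itself mark an siRNA site. The 4 of 4 comparisons by number of sites cover only AGCAGTT and AGCCTTA, and for AGCAGTT the differences were within their standard errors. Seed pairing would give such differences, and a second siRNA against YES1 and a second control would test it.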
